A study of Mus musculus with 70 samples.

How the data were processed

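RNA of macrophages grown from bone marrow of C57BL/6 mice in M-CSF (60 ng per ml, 6 days per the labels) was hybridized to Illumina bead arrays. Per the labels the cells were untreated or stimulated with R848, poly(I:C), Pam3CSK4, LPS or a pair of these for 1, 4 or 8 h. Doses were not used here. The deposited non-normalized values give the average bead signal per probe as an intensity on the linear scale, without background subtraction, from 84.1 to 25497. Beside each intensity the deposited table gives a detection p-value per probe and array, per the file headers. The authors' normalized values are log2 values in which every array has the same distribution: sorted values differed by at most 0 between arrays, and the series' own matrix held the same values. It lists 19463 probes. Of the 6234 others none was detected at p under 0.05 on 2 or more arrays. GenomeStudio 2011.1 is named per the submitters' processing notes.

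Groups were taken from the labels. The 70 arrays on 9 slides held 66 RNA extracts, 2 in each of 33 groups, and 4 untreated extracts at 1 and 4 h had 2 arrays each, which were averaged. Each slide held 1 time point. The intensities were background-corrected and quantile-normalized over all arrays with neqc in limma 3.58.1 (R 4.3.3, data.table version 1.17.8), using the detection p-values and an offset of 16, and taken to log2. A probe was kept if its detection p was under 0.01 on every array of at least 1 group (11503 probes). Of the probes in the arrays' annotation 18414 listed 1 gene symbol and 0 listed several. The 10878 named probes past the filter gave 8039 genes, with the brightest probe taken where a gene had several (2062 genes). Symbols were not merged over synonyms, and 85 tested symbols are only an older symbol of another tested gene. The 625 probes without a gene name stayed out of the comparisons. A limma model with 1 mean per group was fitted with empirical Bayes variances (33 residual and 5.41 prior degrees of freedom). Between the extracts of a group the median absolute difference was 0.161 log2 (from 0.125 to 0.41 over groups), and between repeat arrays 0.116 to 0.165.

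The comparisons were each single ligand and each pair against untreated cells of the same time, each pair against the sum of its single responses, each treatment's response at 8 h against that at 4 h, and ligand against ligand at 4 h. Tests were two-sided limma tests with Benjamini-Hochberg adjusted p-values within each contrast, and a gene was called at adjusted p under 0.05 and a change of at least 2-fold. The sum of a pair was the linear level of each ligand added together, less the untreated level. The difference in log2 was tested with a delta-method standard error, for genes with a sum of at least 0.5 times the untreated level, and called at 1.5-fold. Gene lists were tested with fry, with p-values adjusted over lists and contrasts of a family, and their members were also adjusted over the list alone. The lists were immediate-early genes, inflammatory cytokines, chemokines, interferon beta and interferon-stimulated genes, negative feedback regulators, inducible effector genes, glycolysis, citrate cycle and respiratory chain, sterol biosynthesis, cell division, TLR receptors and adaptors, MHC class I and class II antigen presentation, co-stimulatory molecules, resting macrophage genes, and markers of neutrophils, dendritic cells, T cells, NK cells, B cells, erythroid cells, mast cells and basophils, and stromal cells and fibroblasts. Genes were named by rule: members of the lists with the largest changes, the 5 highest and 5 lowest called genes of each single ligand at 4 h, of each pair against the sum at 4 and 8 h, and of each treatment at 8 h against 4 h, and a set of check genes. The lists, the rule, the thresholds and the alternatives were fixed before the data were examined, except for leaving out 3 extracts that stood apart from their partners.

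The alternatives were the authors' normalized values, no background correction, scaling each array to the same median in place of quantile normalization, no detection filter, slide as a block, the run of extract numbers as a block, each time on its own, the earlier of the repeat arrays, the mean of all probes of a gene, the product of the single folds in place of the sum, other limits on the sum, leaving out each extract in turn, and leaving out the 3 extracts. Steps were tested on data simulated from the residual spread, not with shifts by run, slide or extract. Against untreated, between times and between ligands, 89.6 to 100 percent of 3-fold and 98.5 to 100 percent of 6-fold changes were recovered. All simulations gave 0 to 4 false calls per direction. Against the sum 50.7 to 59.7 percent of 2-fold and 81.8 to 93.9 percent of 4-fold differences were recovered. Fry gave p under 0.05 for 100 percent of lists shifted by 0.5 log2 and 3 percent of lists not shifted. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.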

Results

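Transcripts were measured on Illumina bead arrays in macrophages grown from mouse bone marrow with M-CSF. The cells were left untreated or stimulated for 1, 4 or 8 h with R848, poly(I:C), Pam3CSK4 or LPS, or with 1 of the 6 pairs of these ligands. R848 is sensed by TLR7 and Pam3CSK4, a bacterial lipopeptide mimic, by TLR1 and TLR2, both through the adaptor MyD88. Poly(I:C), a mimic of double-stranded RNA, is sensed by TLR3 through the adaptor TRIF and by MDA5 in the cytoplasm, and LPS is sensed by TLR4 through both adaptors. The 33 groups (11 conditions at 3 times) held 2 RNA extracts each, on 70 arrays in all, because 4 untreated extracts were measured on 2 arrays each. Array medians lay between 102 and 123.6 intensity units, and 32.3 to 42.4 percent of the probes were detected per array. The number of arrays limits the precision. The labels do not say that the extracts of a group came from separate cultures, so the p-values measure the spread between these samples. The comparisons ask what each ligand changed, and whether a pair gave more or less than its ligands apart. Changes are given as log2 ± standard error, with 2 extracts per group, and 8039 genes were tested. In 3 extracts 10 or more genes lay over 4-fold below the partner extract.

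Within 1 h each ligand raised genes for neutrophil-attracting chemokines, inflammatory cytokines and their inhibitors. Cxcl1, which encodes such a chemokine, rose by 7.40 ± 0.21 with R848, 5.49 ± 0.21 with poly(I:C), 7.56 ± 0.21 with Pam3CSK4 and 7.86 ± 0.21 with LPS. Tnf, a central inflammatory cytokine, rose 33-fold, 24.2-fold, 33.2-fold and 50.7-fold in the same order. Socs3, an inhibitor of cytokine receptor signalling, rose by 6.75 ± 0.16, 4.77 ± 0.16, 6.56 ± 0.16 and 7.21 ± 0.16. Ifnb1, the gene of interferon beta, rose with poly(I:C) (5.05 ± 0.37) and LPS (6.38 ± 0.37), while its change was 0.87 ± 0.37 with R848 and 0.40 ± 0.37 with Pam3CSK4. Of 15 measured chemokine genes, 7, 6, 7 and 8 rose with R848, poly(I:C), Pam3CSK4 and LPS (7, 7, 7 and 8 adjusted over the list alone). Of 22 inflammatory cytokine genes 8, 5, 7 and 11 rose (the same adjusted over the list alone). The 23 negative feedback regulators, such as Socs3 and Tnfaip3 (5.14 ± 0.27 with LPS), gave 15, 13, 13 and 15 rises (the same adjusted over the list alone). Atf3 of that list fell with Pam3CSK4 (-1.51 ± 0.26). The 23 inducible effector genes gave 13, 1, 9 and 14 rises (13, 2, 11 and 15 adjusted over the list alone). Ch25h, which makes an antiviral oxysterol, rose by 4.54 ± 0.29 with LPS. Co-stimulatory genes, 10 measured, gave 5, 4, 5 and 7 rises (the same adjusted over the list alone), and Cd40 rose by 4.61 ± 0.19 with LPS. Among 22 genes for TLR receptors and adaptors 6, 1, 5 and 6 rose (the same adjusted over the list alone). Tlr2 rose by 1.75 ± 0.17, 1.64 ± 0.17, 1.79 ± 0.17 and 2.14 ± 0.17. The TLR list's count with Pam3CSK4 was 3 without untreated 1 h replicate 1. Among 19 immediate-early genes, which respond to signals without new protein synthesis, 7, 8, 8 and 10 rose (the same adjusted over the list alone). Dusp2, a phosphatase, rose by 5.56 ± 0.16 with LPS, while Fos fell with R848 (-1.61 ± 0.29) and LPS (-1.99 ± 0.29). Of the 44 interferon beta and interferon-stimulated genes 5, 3, 4 and 9 rose at this time (the same adjusted over the list alone). With Pam3CSK4 it was 2 without untreated 1 h replicate 1. Sertad3 fell with LPS (-1.71 ± 0.18).

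Across all genes tested with limma, 267 rose and 97 fell with R848 at 1 h, 82 rose and 18 fell with poly(I:C), 203 rose and 47 fell with Pam3CSK4 and 334 rose and 151 fell with LPS. Leaving out 1 extract moved the total of R848 from 364 to 670 without R848 1 h replicate 2. That of poly(I:C) moved from 100 to 63 without poly(I:C) 1 h replicate 2 and 255 without poly(I:C) 1 h replicate 1. With each array scaled to 1 median in place of quantile normalization, 239 and 181 rose and fell with R848 and 166 and 79 with Pam3CSK4. With the authors' normalized values 209 and 44 rose and fell with LPS. R848 1 h replicate 1 stood apart from its partner, with 60 genes over 4-fold lower. Without the 3 extracts of this kind 279 and 106 rose and fell with R848 and 116 and 24 with poly(I:C).

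At 4 h poly(I:C) and LPS raised most of the interferon genes. Poly(I:C) raised 41 and LPS 41 of the 44 interferon-stimulated genes, against 10 with R848 and 8 with Pam3CSK4 (the same adjusted over the list alone). The list's median change was 0.58 with R848, 2.22 with poly(I:C), 0.28 with Pam3CSK4 and 2.31 with LPS. Gbp5, a guanylate-binding protein of cell-autonomous defence, rose by 6.28 ± 0.32 with poly(I:C) and 6.89 ± 0.32 with LPS. Mx1, an antiviral GTPase, rose by 4.92 ± 0.48 and 5.15 ± 0.48. Fry, which tests whether a list's genes move one way on balance and not against other genes, gave adjusted p = 0.00109, 1.25e-15, 0.0579 and 6.61e-16 in the order R848, poly(I:C), Pam3CSK4, LPS. Without untreated 4 h replicate 2 the count with Pam3CSK4 was 3. Genes of the MHC class I pathway, which loads peptides for T cells, rose 1, 6 and 8 of 14 times with R848, poly(I:C) and LPS (the same adjusted over the list alone). Tap1, a peptide transporter gene, rose by 2.57 ± 0.22 with poly(I:C) and 2.88 ± 0.22 with LPS. The LPS count was 5 without untreated 4 h replicate 2, and the list's median with Pam3CSK4 was 0.12.

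R848 and Pam3CSK4 gave large rises of inflammatory genes at 4 h. With R848 the genes that rose most were Cxcl2 (6.71 ± 0.26) and Cxcl1 (6.68 ± 0.21), then Socs3 (6.30 ± 0.16), Hcar2 (5.91 ± 0.26), a receptor for nicotinic acid, and Clecsf9 (5.78 ± 0.20), an older symbol of Clec4e, the gene of the lectin Mincle. With Pam3CSK4 they were Cxcl1 (6.48 ± 0.21), Cxcl2 (6.16 ± 0.26), Socs3 (5.75 ± 0.16), and Clec4e (5.53 ± 0.22, and 5.41 ± 0.20 for its probe listed as Clecsf9). Poly(I:C) raised the T-cell-attracting chemokine genes Cxcl10 (6.51 ± 0.23, 91.3-fold) and Cxcl9 (5.88 ± 0.44), the activation marker Cd69 (6.50 ± 0.15) and the transcription factor gene Pou3f1 (5.22 ± 0.26). LPS raised Il27 (6.89 ± 0.22), Il1a (6.89 ± 0.24), Cd69 (6.74 ± 0.15) and Cxcl10 (6.54 ± 0.23), with adjusted p = 4.1e-26 for Il27. Of 22 cytokine genes 11, 7, 10 and 16 rose with R848, poly(I:C), Pam3CSK4 and LPS (the same adjusted over the list alone). Of 15 chemokine genes 11, 7, 9 and 10 rose (11, 7, 10 and 10 adjusted over the list alone). Il10, an anti-inflammatory cytokine gene, rose by 4.43 ± 0.20, 3.88 ± 0.20, 3.03 ± 0.20 and 4.37 ± 0.20. Il6 rose with LPS (3.17 ± 0.33) and was -0.10 ± 0.33 with poly(I:C) and 0.84 ± 0.33 with Pam3CSK4. Of 23 effector genes 18, 13, 17 and 22 rose (the same adjusted over the list alone). With LPS Hdc, which makes histamine, rose by 6.42 ± 0.20, and Nos2, which makes nitric oxide, by 4.60 ± 0.31. With R848 Ptges, a prostaglandin E synthase, rose by 4.84 ± 0.18. The feedback regulators gave 18, 11, 15 and 19 rises of 23 (the same adjusted over the list alone). Rgs1 fell with Pam3CSK4 (-1.20 ± 0.28).

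Genes that fell at 4 h included receptors, DNA replication genes and genes of resting macrophages. Cxcr4, a chemokine receptor, fell with R848 (-4.93 ± 0.20), poly(I:C) (-2.83 ± 0.20), Pam3CSK4 (-4.36 ± 0.20) and LPS (-5.13 ± 0.20). Cnr2, a cannabinoid receptor, fell with R848 (-4.41 ± 0.14), poly(I:C) (-3.02 ± 0.14) and Pam3CSK4 (-4.18 ± 0.14). With LPS the deepest falls were Lhfpl2 (-5.30 ± 0.22), Cxcr4, Plekhg3 (-5.02 ± 0.18) and Tmem86a (-5.01 ± 0.27). Gpr146 fell furthest with poly(I:C) (-3.21 ± 0.23). Of 21 cell division genes 10, 1, 11 and 16 fell with R848, poly(I:C), Pam3CSK4 and LPS (11, 1, 11 and 16 adjusted over the list alone). Among them were the replication helicase genes Mcm2 (-2.01 ± 0.23 with R848, -2.03 ± 0.23 with Pam3CSK4, -1.68 ± 0.23 with LPS) and Mcm6 (-2.17 ± 0.30 with R848). Without untreated 4 h replicate 2 these counts were 6 with R848, 5 with Pam3CSK4 and 10 with LPS. With Pam3CSK4 it was 6 without Pam3CSK4 4 h replicate 1. The poly(I:C) count was 3 without poly(I:C) 4 h replicate 2 and 3 without untreated 4 h replicate 1. Without background correction 5, 5 and 3 fell with R848, Pam3CSK4 and LPS. Of 23 resting macrophage genes 5, 1, 5 and 6 fell (the same adjusted over the list alone). Mertk, a receptor for dying cells, was among them (-3.10 ± 0.20 with R848 and -2.78 ± 0.20 with Pam3CSK4). The LPS count was 3 without LPS 4 h replicate 2. Klf4 rose with LPS (1.08 ± 0.18), a call that ended without LPS 4 h replicate 1 (0.85). Sterol biosynthesis genes rose 4, 3 and 1 of 16 times with R848, Pam3CSK4 and LPS (the same adjusted over the list alone). Hsd17b7 rose by 1.64 ± 0.21 with R848 and 1.63 ± 0.21 with Pam3CSK4, and Mvd fell with LPS (-1.18 ± 0.17). The list's median with poly(I:C) was -0.12. Of 14 glycolysis genes 3, 3 and 5 rose with R848, Pam3CSK4 and LPS (the same adjusted over the list alone). The glucose transporter gene Slc2a1 rose 3.9-fold, 4.08-fold and 3.69-fold. Of 22 TLR genes 9, 7, 9 and 11 rose (9, 8, 9 and 11 adjusted over the list alone). Tlr4, the LPS receptor, fell with R848 (-1.67 ± 0.15) and Pam3CSK4 (-2.31 ± 0.15). Tlr3 rose with poly(I:C) (1.76 ± 0.22). Co-stimulatory genes rose 4, 5, 4 and 8 of 10 times (the same adjusted over the list alone). H2-DMa of the MHC class II pathway fell with R848 (-1.15 ± 0.19).

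With limma 572 rose and 665 fell with R848 at 4 h, 561 rose and 365 fell with poly(I:C), 455 rose and 503 fell with Pam3CSK4 and 929 rose and 1053 fell with LPS. With median scaling the numbers that rose and fell were 467 and 869, 410 and 691, 343 and 725 and 703 and 1581. That scaling moved the median of all genes by -0.55 to 0.17 over all contrasts. The authors' normalized values gave 968 changed genes with LPS and values without background correction 973, against 1982. With slide as a block, 570 and 684 rose and fell with R848, 555 and 371 with poly(I:C), 456 and 507 with Pam3CSK4 and 953 and 1078 with LPS. The interferon list's medians were then 0.51, 2.22, 0.28 and 2.36. Within single slides those medians were 0.44 and 0.56 with R848, 2.15 and 2.22 with poly(I:C), 0.17 and 0.19 with Pam3CSK4 and 2.21 and 2.58 with LPS. The cytokine list's medians within the same slides were 0.76 and 1.16, 0.21 and 0.13, 0.47 and 1.11, and 3.05 and 2.81. Those of cell division were -0.90 and -0.82, -0.51 and -0.18, -0.97 and -0.89, and -1.27 and -1.46.

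**Figure D1:**
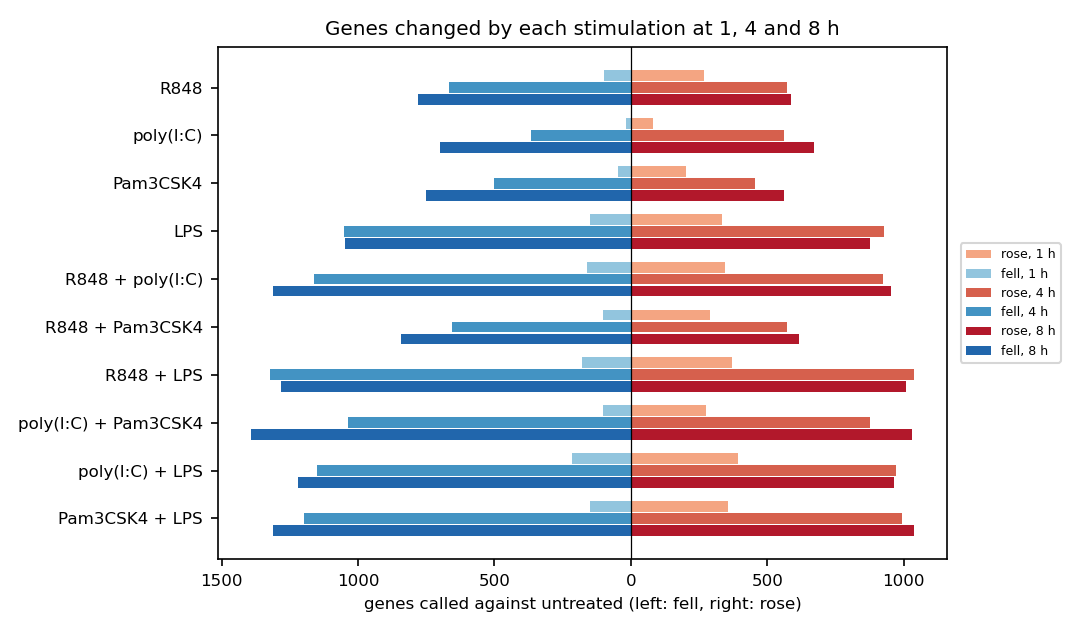
Bars show the number of genes called against untreated for each stimulation (vertical axis) at 1, 4 and 8 h, falls to the left and rises to the right (horizontal axis, genes). With LPS 929 genes rose and 1053 fell at 4 h, against 561 and 365 with poly(I:C).

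At 8 h inflammatory genes stood high under every single ligand, and cell division genes fell. Il1b, an inflammatory cytokine gene, rose by 7.68 ± 0.21 with R848, 3.69 ± 0.21 with poly(I:C), 7.79 ± 0.21 with Pam3CSK4 and 7.87 ± 0.21 with LPS. Cxcl10 rose by 5.19 ± 0.23, 8.76 ± 0.23, 5.84 ± 0.23 and 7.89 ± 0.23. Lcn2, which withholds iron from bacteria, rose with R848 (5.59 ± 0.24), Pam3CSK4 (4.79 ± 0.24) and LPS (7.05 ± 0.24). Of the interferon-stimulated genes 16, 40, 16 and 40 rose with R848, poly(I:C), Pam3CSK4 and LPS (16, 40, 17 and 40 adjusted over the list alone). Gbp2 rose by 3.82 ± 0.25, 6.38 ± 0.25, 3.77 ± 0.25 and 6.31 ± 0.25. Ifnb1 rose with poly(I:C) (6.43 ± 0.37) and LPS (1.93 ± 0.37) and was 0.25 ± 0.37 with R848 and 0.49 ± 0.37 with Pam3CSK4. Cytokine genes gave 13, 10, 11 and 15 rises (the same adjusted over the list alone) and chemokine genes 11, 10, 11 and 10 (the same adjusted over the list alone). Effector genes gave 20, 19, 20 and 22 (the same adjusted over the list alone) and feedback regulators 15, 14, 15 and 17 (the same adjusted over the list alone). Rgs1 fell with R848 (-2.77 ± 0.28) and Pam3CSK4 (-2.93 ± 0.28). MHC class I genes gave 1, 9, 2 and 9 rises (the same adjusted over the list alone), and Tap1 rose by 3.07 ± 0.22 with poly(I:C) and 3.22 ± 0.22 with LPS. The Pam3CSK4 count was 4 without Pam3CSK4 8 h replicate 1. TLR genes gave 8, 8, 8 and 11 rises (the same adjusted over the list alone), with Tlr1 at 2.78 ± 0.20 with R848. Co-stimulatory genes gave 5, 7, 5 and 7 (the same adjusted over the list alone). Cd86 fell with R848 (-1.61 ± 0.25) and Pam3CSK4 (-1.53 ± 0.25) and rose with poly(I:C) (2.66 ± 0.25).

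Cell division genes fell 18, 12, 18 and 19 times of 21 at 8 h (18, 13, 18 and 19 adjusted over the list alone). Tk1, a thymidine kinase, was among them, at -2.77 ± 0.39 with R848, -1.61 ± 0.39 with poly(I:C), -2.52 ± 0.39 with Pam3CSK4 and -3.39 ± 0.39 with LPS. Tpx2 rose with poly(I:C) (1.98 ± 0.20) and LPS (1.70 ± 0.20). Without untreated 8 h replicate 2 the count was 11 with R848 and 5 with poly(I:C), and the latter was 4 without poly(I:C) 8 h replicate 1. Without background correction 9, 2, 8 and 12 fell. Resting macrophage genes fell 9, 7, 8 and 9 times (the same adjusted over the list alone). They included Hpgd, which degrades prostaglandins (-3.74 ± 0.42, -2.73 ± 0.42, -3.72 ± 0.42 and -3.41 ± 0.42), and Gas6 (-2.61 ± 0.11, -1.44 ± 0.11, -2.49 ± 0.11 and -2.12 ± 0.11). The poly(I:C) count was 4 without poly(I:C) 8 h replicate 1. Of 22 citrate cycle and respiratory chain genes 2, 2, 2 and 2 fell (the same adjusted over the list alone). These were Idh1 (-1.89 ± 0.32 with R848 and -2.11 ± 0.32 with LPS) and Idh2 (-1.42 ± 0.29 and -1.79 ± 0.29) under each ligand. Glycolysis genes gave 3, 3, 3 and 4 rises (the same adjusted over the list alone). The LPS citrate cycle count was 4 without untreated 8 h replicate 1 and the poly(I:C) glycolysis count 1 without poly(I:C) 8 h replicate 1. Of 8 MHC class II pathway genes 2, 2 and 1 fell with R848, Pam3CSK4 and LPS (the same adjusted over the list alone). H2-DMa fell with R848 (-2.11 ± 0.19) and Pam3CSK4 (-1.74 ± 0.19), and Ifi30 with R848 (-1.67 ± 0.19), Pam3CSK4 (-1.34 ± 0.19) and LPS (-1.38 ± 0.19). The R848 count was 4 without untreated 8 h replicate 2. The sterol genes Dhcr7 and Msmo1 fell with LPS (Dhcr7 -1.41 ± 0.25). The immediate-early genes still rose 5, 3, 5 and 5 times of 19 (the same adjusted over the list alone), led by Dusp2 (5.72 ± 0.16 with LPS). With limma 588 rose and 780 fell with R848, 670 rose and 700 fell with poly(I:C), 563 rose and 752 fell with Pam3CSK4 and 877 rose and 1048 fell with LPS. Poly(I:C) 8 h replicate 1 had 241 genes over 4-fold below its partner. Without the 3 extracts of this kind 636 and 592 rose and fell with poly(I:C). With median scaling 461 and 956 rose and fell with Pam3CSK4 and 598 and 1871 with LPS.

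Slide as a block gave these numbers that rose and fell at 8 h: 589 and 786 with R848, 671 and 714 with poly(I:C), 566 and 757 with Pam3CSK4 and 916 and 1107 with LPS. At 1 h it gave 275 and 114, 121 and 22, 208 and 52 and 349 and 158. The interferon list's medians at 8 h with that block were 0.62, 2.24, 0.66 and 2.51. Within single slides they were 0.25 and 1.08 with R848, 2.21 and 2.77 with poly(I:C), 0.38 and 1.19 with Pam3CSK4 and 2.17 on the lone slide with LPS and untreated cells. The cytokine medians within the same slides were 1.38 and 1.28, 0.48 and 0.62, 1.13 and 1.44 and 2.46. The cell division medians there were -1.67 and -1.66, -1.05 and -1.01, -1.59 and -1.64 and -2.33. At 1 h the cytokine medians within slides were 0.51 and 0.64 with R848, 0.16 and 0.15 with poly(I:C), 0.32 and 0.49 with Pam3CSK4 and 1.14 and 0.93 with LPS.

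Markers of other cells were few. Among 4 measured neutrophil genes Camp rose with R848 at 4 h (1.95 ± 0.22) and 8 h (3.11 ± 0.22). S100a8 rose at 8 h with R848 (1.64 ± 0.22) and Pam3CSK4 (1.08 ± 0.22, but under 2-fold, 0.88, without untreated 8 h replicate 2). It gained 3.27 ± 0.31 from 4 to 8 h with R848 + poly(I:C). S100a9 fell at 8 h with LPS (-1.37 ± 0.26). Pdgfrb, 1 of 5 measured stromal genes, rose 2.82-fold with LPS at 4 h. Cd79b, the lone B cell gene measured, fell with LPS at 4 h (-1.11 ± 0.29), a call that ended without untreated 4 h replicate 2 (-0.95). The list medians with LPS at 4 h were -0.11 for neutrophils, 0.22 for the 2 dendritic cell genes, -0.09 for the lone NK cell gene Prf1, and 0.57 for stromal cells. No gene of the T cell, erythroid or mast cell and basophil lists passed the detection filter.

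The genes set aside as checks of the labels moved as follows with LPS at 4 h: Tnf 5.07 ± 0.13, Il1b 5.36 ± 0.21, Helz2 2.90 ± 0.26, Phf11d 3.39 ± 0.36 and Zscan12 -1.40 ± 0.16. Helz2, an interferon-responsive helicase, also rose with R848 (1.21 ± 0.26), poly(I:C) (2.44 ± 0.26) and Pam3CSK4 (1.12 ± 0.26). Its calls with R848 and Pam3CSK4 ended without untreated 4 h replicate 2 (0.98 and 0.89). Sertad3 rose 2.83-fold with poly(I:C). The probe for Il12b stayed near the floor, with 0.19 ± 0.17 for LPS, and no probe was listed under Ifit1 or Irg1.

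Direct contrasts between ligands at 4 h differed in interferon and cytokine genes. R848 lay below poly(I:C) for 40 of the 44 interferon-stimulated genes (the same adjusted over the list alone). Among them were Oasl1 (-3.96 ± 0.37), a homologue of the antiviral OAS proteins, and Mx1 (-3.56 ± 0.48). R848 lay below LPS for 39 and Pam3CSK4 below LPS for 41 of them (the same adjusted over the list alone), with Ifnb1 at -4.28 ± 0.37 and -4.24 ± 0.37. Poly(I:C) lay above Pam3CSK4 for 40 (41 adjusted over the list alone). The chemokine genes Cxcl1 (7.22 ± 0.21) and Cxcl2 (6.40 ± 0.26) were higher with R848 than with poly(I:C), and Cxcl9 (-4.36 ± 0.44) and Cxcl10 (-3.06 ± 0.23) lower. Of the cytokine genes 14 were lower with poly(I:C) than with LPS, 9 with R848 and 12 with Pam3CSK4 (the same adjusted over the list alone). Il1a lay at -6.99 ± 0.24 and Edn1, a vasoconstrictor peptide, at -6.43 ± 0.22 for poly(I:C) and Il27 at -3.30 ± 0.22 and -4.69 ± 0.22 for R848 and Pam3CSK4. Sterol genes were higher with R848 than with poly(I:C) (5 genes, such as Sqle 1.66 ± 0.18) or LPS (4, such as Mvd 1.86 ± 0.17). With Pam3CSK4 5 were higher than with LPS, and each of these counts was the same adjusted over the list alone. The last count was 3 without LPS 4 h replicate 2. Mertk (-3.50 ± 0.20) and Tlr4 (-2.30 ± 0.15) were lower with R848 than with poly(I:C). R848 and Pam3CSK4 differed in 8 genes. Edn1 (1.91 ± 0.22), Il10 (1.39 ± 0.20), Il27 (1.39 ± 0.22), Il1a (1.14 ± 0.24) and Il1rn (1.06 ± 0.22) were higher with R848. Cp and Shisa3 were higher too, and Nuak1 was lower. The last 3 were named after their values were seen. That count was 2 without Pam3CSK4 4 h replicate 1 and 3 without R848 4 h replicate 1 or R848 4 h replicate 2. The Il27 call ended in 1 of these fits and those of Il1a and Il1rn in 3, and median scaling left 7 higher and 0 lower. In limma 490 genes were higher and 592 lower with R848 than with poly(I:C), 282 and 489 with R848 than with LPS. They were 537 and 451 with poly(I:C) than with Pam3CSK4, 314 and 369 with poly(I:C) than with LPS, and 382 and 556 with Pam3CSK4 than with LPS. Median scaling gave 435 and 426 for R848 against LPS. The authors' values gave 82 and 262 there, 83 and 195 for poly(I:C) against LPS and 108 and 302 for Pam3CSK4 against LPS. The 6 contrasts with slide as a block gave 493 and 594, 7 and 1, 302 and 511, 539 and 452, 326 and 382 and 401 and 572, in the order R848 against poly(I:C), Pam3CSK4 and LPS, poly(I:C) against Pam3CSK4 and LPS, and Pam3CSK4 against LPS.

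Against untreated cells, pairs that held poly(I:C) or LPS raised the interferon genes and the pair without them raised fewer. At 4 h 39, 11, 40, 40, 41 and 39 of the 44 interferon-stimulated genes rose with R848 + poly(I:C), R848 + Pam3CSK4, R848 + LPS, poly(I:C) + Pam3CSK4, poly(I:C) + LPS and Pam3CSK4 + LPS (the same adjusted over the list alone). At 8 h 38, 17, 41, 41, 41 and 41 rose (the same adjusted over the list alone). Ifnb1 rose at 4 h with R848 + poly(I:C) (5.31 ± 0.37) and Pam3CSK4 + LPS (5.61 ± 0.37). In the same order, cytokine genes gave 18, 12, 18, 16, 15 and 19 rises at 4 h (the same adjusted over the list alone) and 16, 12, 17, 17, 15 and 20 at 8 h (the same adjusted over the list alone). At 8 h Il1a rose by 8.50 ± 0.24, 6.97 ± 0.24, 8.40 ± 0.24, 8.13 ± 0.24, 7.44 ± 0.24 and 9.04 ± 0.24. Effector genes gave 23, 20, 23, 23, 22 and 23 rises at 8 h (23, 21, 23, 23, 22 and 23 adjusted over the list alone). Lcn2 rose by 8.28 ± 0.24 with R848 + poly(I:C) and 8.49 ± 0.24 with R848 + LPS. MHC class I genes gave 8, 2, 10, 10, 11 and 11 rises at 8 h (the same adjusted over the list alone). Tap1 rose by 3.44 ± 0.22 with poly(I:C) + LPS. Cell division genes fell 18, 18, 18, 17, 19 and 18 times at 8 h (the same adjusted over the list alone), with Tk1 at -3.43 ± 0.39 with R848 + LPS. Resting macrophage genes fell 9, 9, 11, 9, 9 and 10 times (the same adjusted over the list alone), and Cx3cr1, the fractalkine receptor, fell with R848 + LPS (-3.38 ± 0.48).

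By gene count, limma called 926 higher and 1161 lower with R848 + poly(I:C), 573 higher and 656 lower with R848 + Pam3CSK4 and 1037 higher and 1324 lower with R848 + LPS at 4 h. It called 877 and 1036 with poly(I:C) + Pam3CSK4, 972 and 1152 with poly(I:C) + LPS and 995 and 1197 with Pam3CSK4 + LPS. At 8 h these numbers were 954 and 1311, 617 and 843, 1010 and 1284, 1032 and 1393, 964 and 1220 and 1039 and 1313 in the same order. At 1 h they were 344 and 161, 370 and 180, 274 and 103, 392 and 217 and 357 and 151 in the pairs other than R848 + Pam3CSK4, with which 391 changed and 290 of these were higher. At 1 h Cxcl1 rose by 7.61 ± 0.21 with R848 + Pam3CSK4 and Ifnb1 by 6.42 ± 0.37 with poly(I:C) + LPS. Slide as a block gave 943 and 1185, 586 and 665, 1056 and 1344, 907 and 1052, 1007 and 1178 and 1021 and 1213 for the 6 pairs at 4 h. At 8 h it gave 997 and 1362, 642 and 890, 1035 and 1342, 1059 and 1407, 976 and 1247 and 1069 and 1343, and at 1 h 364 and 169, 298 and 102, 371 and 192, 264 and 105, 383 and 202 and 343 and 140. In the same order, interferon list medians within slides at 4 h were 2.26 and 2.48, 0.42 and 0.54 and 2.27 and 2.58. The pairs without R848 gave 2.36 and 2.60, 2.43 and 2.71 and 2.26 and 2.55. At 8 h the medians were 2.16, 0.44 and 2.19 on 1 slide and 3.04, 2.88 and 2.45 on another. Only these slides held untreated cells, and between them pair and slide cannot be told apart. Median scaling gave 652 and 1915 with R848 + poly(I:C), 634 and 2468 with R848 + LPS, 704 and 1574 with poly(I:C) + Pam3CSK4, 640 and 2179 with poly(I:C) + LPS and 700 and 2033 with Pam3CSK4 + LPS at 4 h. At 8 h it gave 675 and 1906 with R848 + poly(I:C), 619 and 2405 with R848 + LPS, 660 and 1947 with poly(I:C) + LPS and 837 and 1745 with Pam3CSK4 + LPS. At 1 h it gave 259 and 361 with R848 + poly(I:C), 269 and 152 with R848 + Pam3CSK4, 321 and 312 with R848 + LPS, 214 and 189 with poly(I:C) + Pam3CSK4 and 332 and 362 with poly(I:C) + LPS. The authors' values gave 206 and 51 with R848 + poly(I:C), 224 and 49 with R848 + LPS, 226 and 56 with poly(I:C) + LPS and 217 and 43 with Pam3CSK4 + LPS at 1 h and 545 and 419 with poly(I:C) + Pam3CSK4 at 4 h.

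**Figure D2:**
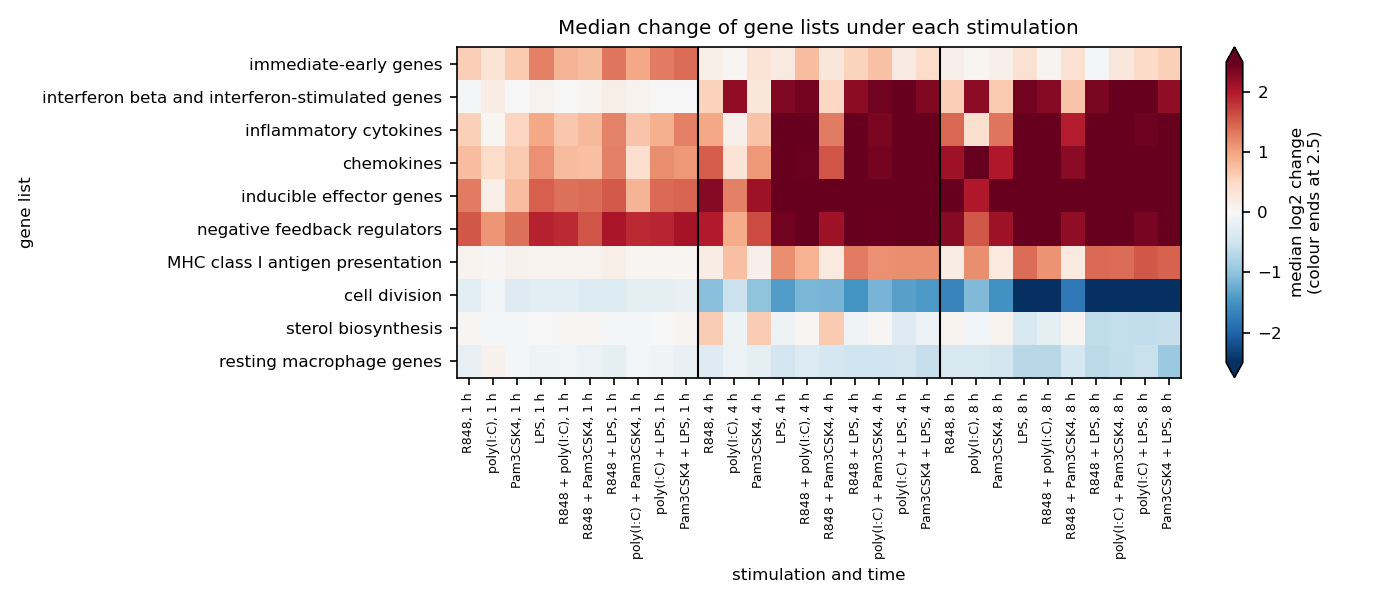
Colours give the median log2 change against untreated of 10 gene lists (vertical axis) under each stimulation at 1, 4 and 8 h (horizontal axis); colours end at 2.5 in either direction. At 4 h the interferon list's median was 2.22 with poly(I:C) and 0.28 with Pam3CSK4.

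Each pair's level was compared with the sum of its single responses, taken on the linear scale. Pairs of R848 or Pam3CSK4 with poly(I:C) or LPS exceeded the sum for some cytokine genes. At 8 h Il19, a cytokine of the IL-10 family, reached 35.7 times the sum (95% interval 29 to 44) with R848 + poly(I:C) and 26.8 times the sum (95% interval 20.9 to 34.2) with poly(I:C) + Pam3CSK4. It reached 13.6 times the sum (95% interval 11.3 to 16.3) with R848 + LPS and 7.57 times the sum (95% interval 6.24 to 9.19) with Pam3CSK4 + LPS. Slamf1, a receptor of leukocytes, lay above the sum by 4.09 ± 0.41, 3.62 ± 0.40, 2.97 ± 0.30 and 2.33 ± 0.29 in the same order. At 4 h Il6 lay above it with R848 + poly(I:C) (2.35 ± 0.37) and poly(I:C) + Pam3CSK4 (2.49 ± 0.38). With the same pairs Edn1 lay above it by 2.53 ± 0.22 and 3.88 ± 0.24, Nos2 by 2.11 ± 0.30 and 2.62 ± 0.31, and Il27 by 2.06 ± 0.19 and 2.48 ± 0.20. Of 22 cytokine genes 8 (13 adjusted over the list alone) lay above the sum at 4 h and 11 (12 adjusted over the list alone) at 8 h with R848 + poly(I:C). These counts were 8 (9 adjusted over the list alone) and 10 (10 adjusted over the list alone) with poly(I:C) + Pam3CSK4. The effector genes above the sum numbered 7 (9 adjusted over the list alone) at 4 h and 13 (13 adjusted over the list alone) at 8 h with the former pair. With the latter they numbered 8 (10 adjusted over the list alone) and 13 (14 adjusted over the list alone), and Lcn2 lay above it by 3.11 ± 0.23 at 8 h. The effector count with R848 + poly(I:C) at 4 h was 4 without R848 4 h replicate 1. The genes furthest below the sum were Kif5c (-2.44 ± 0.22), a kinesin, Uaca (-2.22 ± 0.31) and Hhex (-2.15 ± 0.33) at 4 h with R848 + poly(I:C). At 8 h they were Ccnd1, cyclin D1 (-3.70 ± 0.35), Mmp9, a gelatinase (-2.96 ± 0.38), and Plxna2 (-2.67 ± 0.26). In poly(I:C) + Pam3CSK4 they were Herpud1, a gene of the endoplasmic reticulum stress response (-1.85 ± 0.21), and Egln3 (-1.72 ± 0.26) at 4 h and Mmp9 (-3.81 ± 0.38, -3.02 and -4.59 without poly(I:C) + Pam3CSK4 8 h replicate 1 or 2), Plxna2 (-2.75 ± 0.25), Smad3 (-2.34 ± 0.26) and Ccnd1 (-2.27 ± 0.32) at 8 h.

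The test against the sum used limma's moderated variances. With R848 + poly(I:C) at 4 h 66 genes lay above and 114 below. The number above was 38 without R848 + poly(I:C) 4 h replicate 1, 42 without R848 4 h replicate 2 and 43 without R848 4 h replicate 1. The number below was 66 without R848 + poly(I:C) 4 h replicate 2, 67 without R848 4 h replicate 2 and 74 without R848 4 h replicate 1. At 8 h 162 genes lay above and 638 below with R848 + poly(I:C). Above the sum the number was 286 without poly(I:C) 8 h replicate 2. Below the sum the number was 352 without poly(I:C) 8 h replicate 1 and 1422 without poly(I:C) 8 h replicate 2. With poly(I:C) + Pam3CSK4 at 4 h 90 genes lay above and 193 below. Above, the number became 48 without poly(I:C) + Pam3CSK4 4 h replicate 1. Below, the number became 115 without poly(I:C) + Pam3CSK4 4 h replicate 2, 116 without poly(I:C) + Pam3CSK4 4 h replicate 1 and 119 without Pam3CSK4 4 h replicate 2. At 8 h 202 genes lay above and 703 below with poly(I:C) + Pam3CSK4. The number above was 114 without poly(I:C) + Pam3CSK4 8 h replicate 1. The number below was 374 without poly(I:C) 8 h replicate 1, 408 without poly(I:C) + Pam3CSK4 8 h replicate 1 and 1442 without poly(I:C) 8 h replicate 2. The alternative of median scaling gave 47 above and 45 below for the last pair at 4 h. Slide as a block gave, above and below, 104 and 226 at 4 h and 264 and 833 at 8 h with R848 + poly(I:C) and 142 and 341 and 284 and 820 with poly(I:C) + Pam3CSK4. At 8 h Mmp9 reached 0.129 times the sum (95% interval 0.0764 to 0.217) with R848 + poly(I:C). Against the product of the single folds in place of their sum, Il27 (-0.60) and Hhex (0.09) took the other sign with R848 + poly(I:C) at 4 h. Over the 6 pairs at 4 and 8 h 9666 calls lay above and 8371 below that product, against 808 and 5023 for the sum.

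LPS joined with R848 or Pam3CSK4 gave fewer genes above the sum than below it. With R848 + LPS at 4 h Sele, an adhesion molecule, lay above it by 2.49 ± 0.29, Clcf1 by 2.07 ± 0.24, Il19 by 1.89 ± 0.14 and Errfi1 by 1.75 ± 0.20. At 8 h Scarf2 lay above it by 2.60 ± 0.24, Arg2, an arginase, by 2.56 ± 0.42 and Ptx3, a pattern-recognition protein, by 2.43 ± 0.28. With Pam3CSK4 + LPS, Csf2, the GM-CSF gene, lay above it by 2.29 ± 0.49, Il12a by 1.24 ± 0.20 and Cish by 1.11 ± 0.21 at 4 h. Arg2 lay above it by 2.56 ± 0.44, Ptx3 by 2.33 ± 0.28 and Csf3, the G-CSF gene, by 1.85 ± 0.19 at 8 h. Below it at 8 h lay Mmp9 (-4.33 ± 0.37 with R848 + LPS and -3.70 ± 0.37 with Pam3CSK4 + LPS) and Slc13a3, a transporter of dicarboxylates (-3.87 ± 0.38 and -3.50 ± 0.38). At 4 h it was Slc13a3 (-2.83 ± 0.38 and -2.34 ± 0.38) and Herpud1 (-2.91 ± 0.19 and -2.24 ± 0.19). With R848 + LPS 9 (10 adjusted over the list alone) cytokine genes lay above the sum at 4 h and 6 (8 adjusted over the list alone) at 8 h. With Pam3CSK4 + LPS these counts were 5 (9 adjusted over the list alone) and 11 (14 adjusted over the list alone). The R848 + LPS count at 4 h was 5 without R848 + LPS 4 h replicate 1 and 5 without R848 + LPS 4 h replicate 2. The Pam3CSK4 + LPS count at 4 h was 3 without each of LPS 4 h replicate 1, LPS 4 h replicate 2, Pam3CSK4 + LPS 4 h replicate 1, Pam3CSK4 4 h replicate 1, untreated 4 h replicate 1 and untreated 4 h replicate 2. With R848 + LPS at 4 h 44 genes lay above and 502 below. Above the sum the number was 23 without LPS 4 h replicate 1 and 29 without R848 + LPS 4 h replicate 2. At 8 h 115 genes lay above and 627 below with R848 + LPS. With Pam3CSK4 + LPS at 4 h 18 genes lay above and 320 below. Above, the number became 10 without LPS 4 h replicate 2 and 11 without Pam3CSK4 4 h replicate 1. Below the sum the number was 213 without Pam3CSK4 + LPS 4 h replicate 2. At 8 h 100 genes lay above and 488 below with Pam3CSK4 + LPS. The number above was 66 without Pam3CSK4 + LPS 8 h replicate 2. Below, the number became 304 without Pam3CSK4 + LPS 8 h replicate 2. Against the product of the single folds Il12a (-0.28) and Cish (-0.25) took the other sign with Pam3CSK4 + LPS at 4 h. For Pam3CSK4 + LPS at 8 h median scaling gave 79 above and 163 below. In the fit with slide as a block 99 and 625, 169 and 750, 37 and 451 and 135 and 565 lay above and below in the same order.

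The pairs R848 + Pam3CSK4 and poly(I:C) + LPS stayed at or under the sum for almost every called gene. With poly(I:C) + LPS 16 (25 adjusted over the list alone) of the 44 interferon-stimulated genes lay below it at 4 h and 22 (30 adjusted over the list alone) at 8 h. The list's median ratio to the sum was 0.584 and 0.567. The former count was 9 without LPS 4 h replicate 1, 5 without poly(I:C) + LPS 4 h replicate 1 and 5 without poly(I:C) + LPS 4 h replicate 2. At 8 h the count was 13 without poly(I:C) + LPS 8 h replicate 1 and 10 without poly(I:C) + LPS 8 h replicate 2. Pim1, a kinase (-1.81 ± 0.27, and -1.95 ± 0.27 at 8 h), Kif5c (-1.74 ± 0.20) and Gadd45g (-1.70 ± 0.19) lay furthest below it at 4 h. At 8 h Plxna2 (-2.59 ± 0.29), Klf2 (-2.20 ± 0.31, -1.36 and -3.01 without poly(I:C) 8 h replicate 1 or 2), Mycl (-2.14 ± 0.32) and Dnase1l3 (-2.11 ± 0.19) did. Tob1 lay above it at 4 h (1.09 ± 0.31), a call lost in 8 of the fits that left out 1 extract. With R848 + Pam3CSK4 at 8 h Rasgrf1 (-1.32 ± 0.21), Ndrl (-1.19 ± 0.19) and Igsf9 (-1.18 ± 0.24) lay below the sum. At 4 h the genes furthest below, such as Abcc1, a transporter (-1.81 ± 0.31), lost the call without R848 + Pam3CSK4 4 h replicate 2 (Abcc1 -0.82, adjusted p = 0.18). Abcc1 lay further below without R848 + Pam3CSK4 4 h replicate 1 (-2.81). Of the feedback regulators 11 (12 adjusted over the list alone) lay below the sum with this pair at 8 h. With R848 + Pam3CSK4 at 4 h 0 genes lay above and 331 below. Above the sum the number was 39 without R848 + Pam3CSK4 4 h replicate 1. The number below was 77 without R848 + Pam3CSK4 4 h replicate 2. At 8 h 0 genes lay above and 341 below with R848 + Pam3CSK4. Above, the number became 1 without Pam3CSK4 8 h replicate 2. Below the sum the number was 110 without R848 + Pam3CSK4 8 h replicate 2 and 203 without R848 + Pam3CSK4 8 h replicate 1. In limma 68 genes at 4 h and 33 at 8 h lay above at an unadjusted p under 0.05. The authors' values gave 26 above and 228 below at 4 h, and median scaling 17 below. At 4 h 151 lay below without the 3 extracts that stood apart, 1 of which was R848 + Pam3CSK4 4 h replicate 2. With poly(I:C) + LPS at 4 h 1 gene lay above and 208 below. The number above was 0 without untreated 4 h replicate 1, poly(I:C) 4 h replicate 1, LPS 4 h replicate 1, untreated 4 h replicate 2, poly(I:C) 4 h replicate 2 or poly(I:C) + LPS 4 h replicate 2 and 2 without poly(I:C) + LPS 4 h replicate 1 or LPS 4 h replicate 2. Below, the number became 97 without poly(I:C) + LPS 4 h replicate 2, 114 without poly(I:C) + LPS 4 h replicate 1 and 132 without LPS 4 h replicate 1. At 8 h 10 genes lay above and 558 below with poly(I:C) + LPS. Above the sum the number was 2 without LPS 8 h replicate 1 or poly(I:C) + LPS 8 h replicate 2, 3 without poly(I:C) 8 h replicate 1 or untreated 8 h replicate 2, 4 without untreated 8 h replicate 1, 5 without LPS 8 h replicate 2, 6 without poly(I:C) + LPS 8 h replicate 1 and 74 without poly(I:C) 8 h replicate 2. The number below was 342 without poly(I:C) 8 h replicate 1 and 1286 without poly(I:C) 8 h replicate 2. Slides taken as a block gave, above and below, 5 and 404, 2 and 456, 15 and 303 and 16 and 617 in the same order.

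At 1 h few genes differed from the sum. Il1a lay above it with R848 + poly(I:C) and with poly(I:C) + Pam3CSK4 (1 gene each). Below it lay Fos, Hcar2 and Pim1 with R848 + poly(I:C), poly(I:C) + Pam3CSK4 and poly(I:C) + LPS. Ccl4, Dusp2 and Zfp36 also lay below it with poly(I:C) + LPS, and Dusp1, Nfkbid and Zfp36 with R848 + poly(I:C). These genes were named after their values were seen. The numbers below were 6 with R848 + poly(I:C), 38 with R848 + Pam3CSK4, 87 with R848 + LPS, 3 with poly(I:C) + Pam3CSK4, 6 with poly(I:C) + LPS and 33 with Pam3CSK4 + LPS. None passed above it with R848 + Pam3CSK4, R848 + LPS, poly(I:C) + LPS or Pam3CSK4 + LPS, where 27, 24, 50 and 20 lay above at an unadjusted p under 0.05 in limma. Leaving out 1 extract moved these counts widely. With R848 + poly(I:C) the number below was 3 without R848 + poly(I:C) 1 h replicate 1, R848 + poly(I:C) 1 h replicate 2 or poly(I:C) 1 h replicate 2, 32 without R848 1 h replicate 2 and 56 without poly(I:C) 1 h replicate 1. With R848 + Pam3CSK4 it was 1 without R848 + Pam3CSK4 1 h replicate 2, 8 without R848 + Pam3CSK4 1 h replicate 1, 13 without Pam3CSK4 1 h replicate 2 and 66 without R848 1 h replicate 2. With R848 + LPS it was 28 without R848 + LPS 1 h replicate 2, 36 without R848 + LPS 1 h replicate 1 and 54 without LPS 1 h replicate 1. Poly(I:C) + Pam3CSK4 gave 1 without poly(I:C) + Pam3CSK4 1 h replicate 1 and 77 without poly(I:C) 1 h replicate 1. Poly(I:C) + LPS gave 3 without poly(I:C) + LPS 1 h replicate 1, LPS 1 h replicate 2 or poly(I:C) + LPS 1 h replicate 2 and 87 without poly(I:C) 1 h replicate 1. With Pam3CSK4 + LPS it was 6 without Pam3CSK4 + LPS 1 h replicate 1, 9 without Pam3CSK4 + LPS 1 h replicate 2 and 13 without LPS 1 h replicate 1 or Pam3CSK4 1 h replicate 2. The number above with R848 + poly(I:C) was 0 without R848 + poly(I:C) 1 h replicate 1, R848 1 h replicate 1, R848 + poly(I:C) 1 h replicate 2 or poly(I:C) 1 h replicate 2, 4 without poly(I:C) 1 h replicate 1 and 16 without R848 1 h replicate 2. That with poly(I:C) + Pam3CSK4 was 0 without poly(I:C) + Pam3CSK4 1 h replicate 1, Pam3CSK4 1 h replicate 1, poly(I:C) + Pam3CSK4 1 h replicate 2 or poly(I:C) 1 h replicate 2 and 2 without poly(I:C) 1 h replicate 1 or Pam3CSK4 1 h replicate 2.

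**Figure D3:**
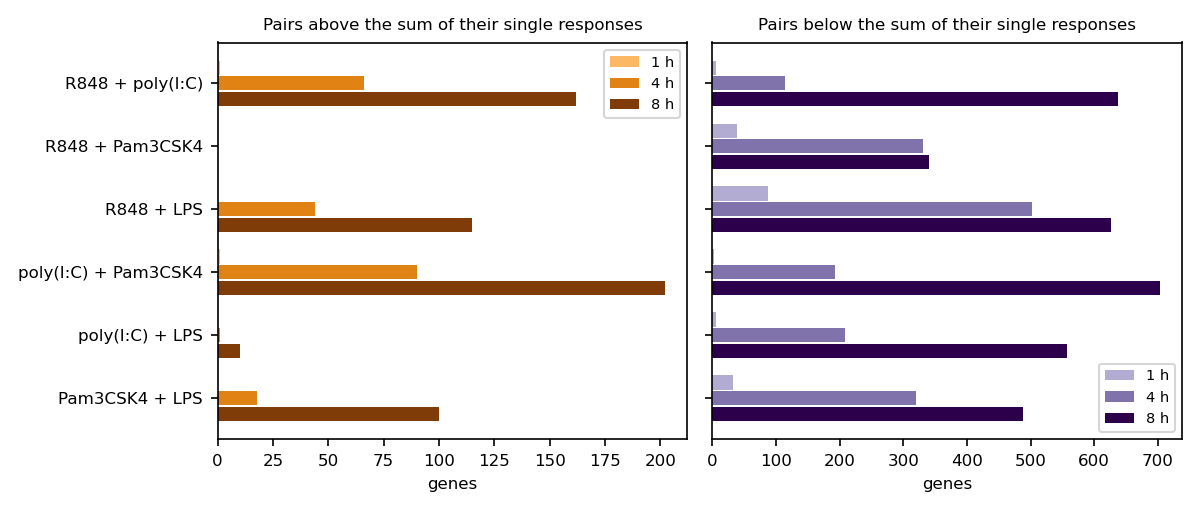
Bars show for each pair (vertical axis) how many genes lay above (left) or below (right) the sum of the single responses at 1, 4 and 8 h (horizontal axes, genes, with different scales). At 8 h 115 genes lay above and 627 below with R848 + LPS.

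**Figure D4:**
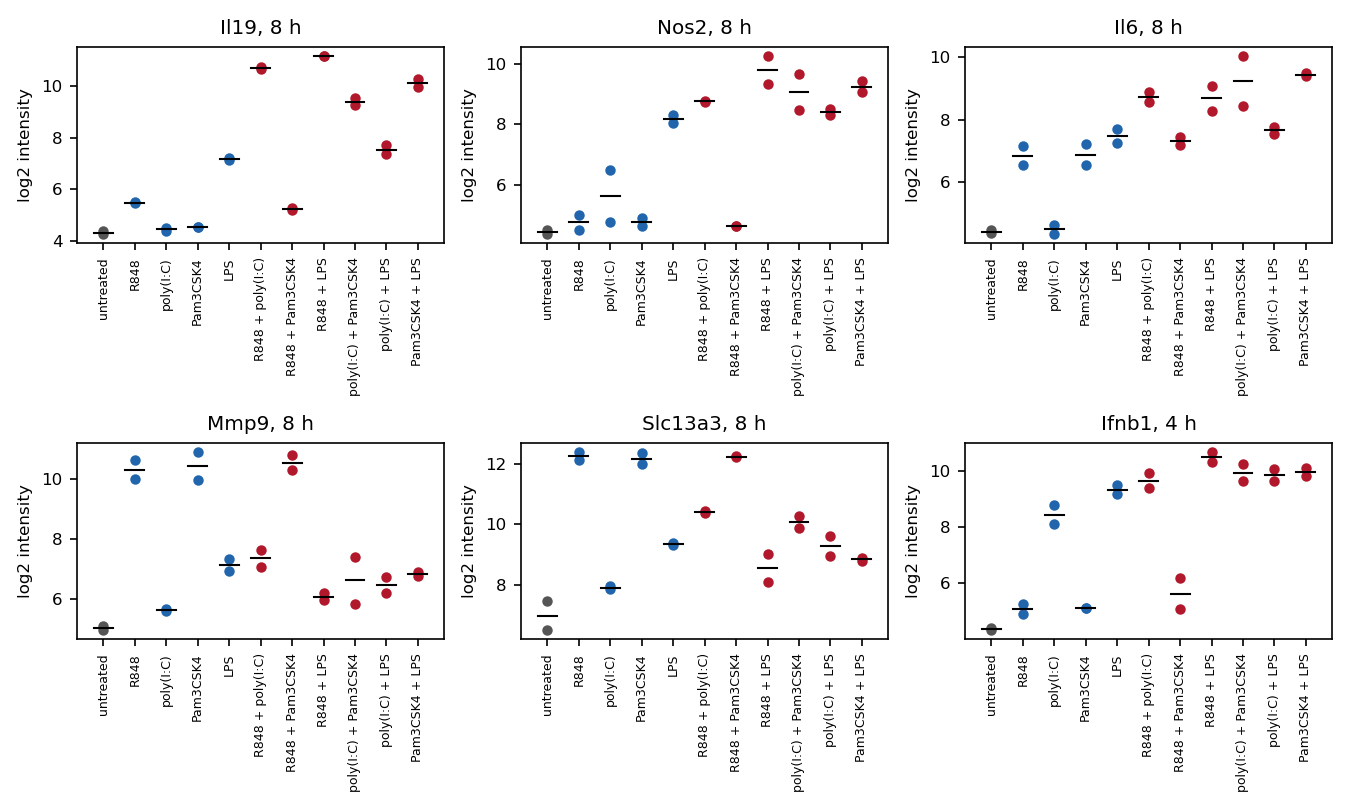
Each point is 1 RNA extract and each black line the mean of 2 extracts (vertical axes, log2 intensity; horizontal axes, untreated cells in grey, single ligands in blue, pairs in red) for Il19, Nos2, Il6, Mmp9 and Slc13a3 at 8 h and Ifnb1 at 4 h. Il19 reached 35.7 times the sum (95% interval 29 to 44) with R848 + poly(I:C), and Mmp9 0.0497 times the sum (95% interval 0.0299 to 0.0824) with R848 + LPS.

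Between 4 and 8 h, changes against untreated cells grew for Il1b and for effector genes. Il1b gained 2.19 ± 0.29 with R848, 4.25 ± 0.29 with poly(I:C), 2.52 ± 0.29 with Pam3CSK4 and 2.51 ± 0.29 with LPS. Hp, the gene of haptoglobin, gained 2.08 ± 0.28 with R848 and 3.01 ± 0.28 with LPS. Lcn2 gained 2.75 ± 0.33 with LPS, 3.69 ± 0.33 with R848 + poly(I:C) and 4.01 ± 0.33 with poly(I:C) + Pam3CSK4. Ifnb1 differed by -3.05 ± 0.52 with LPS, -4.27 ± 0.52 with R848 + LPS and -3.50 ± 0.52 with Pam3CSK4 + LPS and gained 2.34 ± 0.52 with poly(I:C). Hhex, a transcription factor gene, differed by -3.80 ± 0.37 with LPS, -4.39 ± 0.37 with poly(I:C) + Pam3CSK4 and -4.15 ± 0.37 with poly(I:C) + LPS. The effector list gained with every single ligand (fry, adjusted p at most 8.68e-07). Of its genes 11 (11 adjusted over the list alone) gained with R848 + poly(I:C), 11 (11) with poly(I:C) + Pam3CSK4 and 10 (11) with Pam3CSK4 + LPS. Of 21 cell division genes 4 (8) were lower at 8 h than at 4 h with LPS (Cdk1, Mcm5, Mcm2 and Mcm4), 1 without LPS 4 h replicate 2, untreated 4 h replicate 1 or untreated 8 h replicate 2 and 2 without LPS 8 h replicate 1. The interferon list's median difference lay at -0.04 with LPS, 0.17 with poly(I:C), 0.11 with R848 and 0.63 with Pam3CSK4.

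By gene count, limma called 55 higher and 57 lower with R848, 299 higher and 187 lower with poly(I:C), 36 higher and 41 lower with Pam3CSK4 and 344 higher and 246 lower with LPS at 8 h than at 4 h. In pairs it called 293 and 278 with R848 + poly(I:C), 46 and 68 with R848 + Pam3CSK4, 577 and 402 with R848 + LPS, 339 and 275 with poly(I:C) + Pam3CSK4, 346 and 323 with poly(I:C) + LPS and 432 and 328 with Pam3CSK4 + LPS. The total with R848 was 71 without untreated 8 h replicate 2 and 72 without untreated 4 h replicate 1. With Pam3CSK4 it was 38 without untreated 4 h replicate 1, 46 without untreated 8 h replicate 2 and 51 without Pam3CSK4 4 h replicate 1. The poly(I:C) total was 300 without poly(I:C) 8 h replicate 1 and 1464 without poly(I:C) 8 h replicate 2, and with R848 + Pam3CSK4 73 without untreated 4 h replicate 1. Large losses under poly(I:C) shrank without poly(I:C) 8 h replicate 1. Tlr8 (-3.18 ± 0.93) was then -1.33, Cited2 (-3.31 ± 0.81) -1.52 and Tnfrsf1a (-3.08 ± 0.81) -1.30, and none passed. Without the 3 extracts that stood apart, Cited2 (adjusted p = 0.0049) and Tnfrsf1a (adjusted p = 0.031) passed at the same values and Tlr8 did not. The Tlr8 call ended in 6 of the fits that left out 1 extract, among them those without poly(I:C) 4 h replicate 1, poly(I:C) 4 h replicate 2 and untreated 8 h replicate 1. Taking slide as a block gave 86 and 102, 342 and 300, 65 and 75, 368 and 305, 331 and 350, 73 and 119, 591 and 446, 406 and 351, 436 and 377 and 507 and 396 in the same order. Median scaling gave 29 and 18 with R848, 338 and 96 with poly(I:C), 22 and 8 with Pam3CSK4, 218 and 240 with LPS, 323 and 164 with poly(I:C) + Pam3CSK4, 346 and 152 with poly(I:C) + LPS and 539 and 177 with Pam3CSK4 + LPS.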

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

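The tests of background correction, of a MyD88-only with a TRIF-using ligand, of RNA or labelling quality, of a response to the treatment and of an exchange of samples were chosen only after the result was seen. In every treatment the response against untreated at 8 h differed from that at 4 h for some genes, by limma's test of the difference itself. These were 112 genes with R848, 486 with poly(I:C), 77 with Pam3CSK4 and 590 with LPS. In pairs they were 571 with R848 + poly(I:C), 114 with R848 + Pam3CSK4, 979 with R848 + LPS, 614 with poly(I:C) + Pam3CSK4, 669 with poly(I:C) + LPS and 760 with Pam3CSK4 + LPS. Counts for R848, Pam3CSK4, poly(I:C) and R848 + Pam3CSK4 moved when 1 extract was left out, as given above.

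Probes without a gene name, 625 past the detection filter and outside every comparison, also changed against untreated at 4 h. With R848 77 changed (36 rose), with poly(I:C) 61 (42 rose), with Pam3CSK4 59 (28 rose) and with LPS 148 (66 rose).

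Over the 6 pairs at 4 and 8 h, 5023 calls lay below the sum and 808 above it, a ratio of 6.22. Against a ceiling of the array, 3.74 percent of the genes called below had a sum above 0.5 of the highest level. Median scaling gave a ratio of 8.16 but itself moved the median of all genes, so it cannot judge quantile normalization. The product of the single folds gave 0.866, so the direction depended on the reference. No biological explanation was tested.

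Genes above the sum were most numerous in the 4 pairs of R848 or Pam3CSK4 with poly(I:C) or LPS. Background correction of dim signals cannot be told apart from a true excess, since 58.6 percent of those calls at 4 and 8 h stayed called without it and uncorrected background compresses folds by itself. Without the 3 extracts that stood apart 73.4 percent of those at 8 h stayed called in the 2 of these pairs whose test used such an extract, which argues against these extracts as the whole cause. A candidate explanation is the joining of a MyD88-only ligand with a TRIF-using ligand: the lowest of the 4 counts exceeded the highest of the other 2 by 17 genes at 4 h and 90 at 8 h. These gaps were -4 and 64 with the authors' values, -1 and 60 without background correction, 7 and 48 with median scaling, 22 and 119 with slide as a block, 20 and 117 without the 3 extracts and -838 and -525 against the product of folds, so with 6 pairs and a 4 h gap that changes sign this cannot be told apart from other differences between the pairs.

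Hspa8, Eef2 and other genes lay over 4-fold below the partner extract in poly(I:C) 8 h replicate 1 (241 genes), R848 1 h replicate 1 (60) and R848 + Pam3CSK4 4 h replicate 2 (14). A response to the treatment was argued against, since in extracts of other treatments that shared a ligand and the time the lowest median changes of these genes against untreated were 0.19, -0.46 and 0.3 log2, and those of the extracts -2.43, -2.4 and -2.14. An exchange with another sample of the series was argued against as the cause of the loss. Over all other groups the lowest medians were -0.24, -0.46 and -1.29, the last with a lower quartile of -2.03. Without these genes R848 1 h replicate 1 matched R848 + Pam3CSK4 1 h replicate 2 better than its partner (r = 0.788 against 0.622). R848 + Pam3CSK4 4 h replicate 2 matched R848 4 h replicate 2 better (r = 0.64 against 0.558). Both matches shared the extract's run and the partners did not, so they cannot separate an exchange from a shift by run. RNA or labelling quality may be the source: the shared genes were 53, 9 and 7 for the 3 pairings, against 1.8, 0.42 and 0.1 expected if independent, and at least 50 percent of the smaller set. It cannot be told apart from other faults of single extracts, since no measure of RNA quality was analysed here.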

How the results depend on the processing

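Leaving out the 3 extracts was chosen only after the data were seen. Each count of called genes was computed again under the alternatives named here and taken as kept where it stayed within 1.5 times its value. That held for 23 of 82 counts with the authors' values, 23 of 82 without background correction, 56 of 82 with median scaling and 78 of 82 without the detection filter. It held for 61 of 82 with slide as a block, 76 of 82 with each time on its own and 80 of 82 with the earlier repeat array. It held for 3 of 36 with the product of folds, 35 of 36 with any sum above 0, 34 of 36 with a sum of at least the untreated level and 74 of 82 without the 3 extracts. Of the counts that moved, 55 fell and 4 rose with the authors' values, and 26 fell with median scaling. Named genes kept direction and call in 345 of 376 values with the authors' table, 341 of 372 with median scaling, 365 of 375 with slide as a block and 359 of 374 without the 3 extracts. List counts stayed within 1.5 times in 413, 446, 475 and 468 of 480, and in 473 with the mean of all probes. That mean was planned for the gene lists, and its calls at 4 and 8 h were 847 above and 4839 below the sum. The cause was not tested for any count that moved. Signal over background limits dim genes: the array medians lay at 102 to 123.6 intensity units, against a lowest intensity of 84.1, and folds of genes near that floor are compressed where no background is removed.

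With the authors' values, and in parentheses without background correction where it differed, these counts moved. The changes against untreated numbered 203 (205), 584 and 675 (683) at 1, 4 and 8 h for R848 and 61, 455 (460) and 661 (660) at 1, 4 and 8 h for poly(I:C). Called against untreated were 150 (151), 443 (447) and 645 (647) at 1, 4 and 8 h for Pam3CSK4 and 253 (254), 968 (973) and 969 (974) at 1, 4 and 8 h for LPS. Against untreated cells there were 257 (260), 1029 (1032) and 1150 (1158) at 1, 4 and 8 h for R848 + poly(I:C) and 230, 573 (574) and 729 (734) at 1, 4 and 8 h for R848 + Pam3CSK4. Against untreated, the genes changed numbered 273 (275), 1182 (1197) and 1201 (1206) at 1, 4 and 8 h for R848 + LPS and 209, 964 (974) and 1241 (1243) at 1, 4 and 8 h for poly(I:C) + Pam3CSK4. The changes against untreated numbered 282 (285), 1046 (1057) and 1072 (1080) at 1, 4 and 8 h for poly(I:C) + LPS and 260 (262), 1095 (1102) and 1224 (1227) at 1, 4 and 8 h for Pam3CSK4 + LPS. Between the times the counts were 42 (44) for R848 and 186 for poly(I:C). Differing between 8 h and 4 h were 26 for Pam3CSK4 and 203 (202) for LPS. Genes whose response differed between 8 h and 4 h numbered 169 (170) for R848 + poly(I:C) and 40 (39) for R848 + Pam3CSK4. Between the times the counts were 303 (306) for R848 + LPS and 179 (182) for poly(I:C) + Pam3CSK4. Differing between 8 h and 4 h were 211 (216) for poly(I:C) + LPS and 239 (242) for Pam3CSK4 + LPS. The ligand contrasts gave 410 (414) for Pam3CSK4 against LPS and 344 (347) for R848 against LPS. Contrasts of ligands also gave 5 for R848 against Pam3CSK4 and 545 (549) for R848 against poly(I:C). These contrasts also gave 278 (277) for poly(I:C) against LPS and 487 (492) for poly(I:C) against Pam3CSK4. Above the sum there were 26 (24) and 11 (13) at 4 and 8 h for R848 + Pam3CSK4 and 2 at 4 h for poly(I:C) + LPS. Below the sum there were 68 (70) and 323 (325) at 4 and 8 h for R848 + poly(I:C) and 217 (219) at 8 h for R848 + Pam3CSK4. Counts below the sum were 309 (310) and 393 (395) at 4 and 8 h for R848 + LPS and 122 (123) and 357 (361) at 4 and 8 h for poly(I:C) + Pam3CSK4. Lying below the sum were 334 (338) at 8 h for poly(I:C) + LPS and 311 at 8 h for Pam3CSK4 + LPS. Genes above the sum at 1 h numbered 1 with R848 + LPS in the authors' values and 1 with R848 + Pam3CSK4 without background correction.

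In what follows the number in parentheses after a 0 is that of genes at an unadjusted p under 0.05 in limma. With median scaling, genes whose response differed between 8 h and 4 h numbered 47 for R848 and 30 for Pam3CSK4. The sum was exceeded by 0 (20), 29 and 80 at 1, 4 and 8 h for R848 + poly(I:C) and 16 and 49 at 4 and 8 h for R848 + LPS. Counts above the sum were 0 (12), 47 and 124 at 1, 4 and 8 h for poly(I:C) + Pam3CSK4 and 0 (4) and 1 at 4 and 8 h for poly(I:C) + LPS. Lying above the sum were 7 at 4 h for Pam3CSK4 + LPS. The numbers below the sum were 3 and 54 at 1 and 4 h for R848 + poly(I:C) and 2, 17 and 107 at 1, 4 and 8 h for R848 + Pam3CSK4. Genes below the sum numbered 48 at 1 h for R848 + LPS and 1, 45 and 396 at 1, 4 and 8 h for poly(I:C) + Pam3CSK4. Below the sum there were 1 at 1 h for poly(I:C) + LPS and 4, 142 and 163 at 1, 4 and 8 h for Pam3CSK4 + LPS. Without the detection filter, genes above the sum numbered 0 (111) at 1 h for R848 + poly(I:C) and 1 at 8 h for R848 + Pam3CSK4. Above the sum there were 0 (65) at 1 h for poly(I:C) + Pam3CSK4 and 2 at 4 h for poly(I:C) + LPS. With slide as a block, genes whose response differed between 8 h and 4 h numbered 188 for R848 and 140 for Pam3CSK4. Differing between 8 h and 4 h were 192 for R848 + Pam3CSK4. The sum was exceeded by 0 (201), 104 and 264 at 1, 4 and 8 h for R848 + poly(I:C) and 5 and 2 at 4 and 8 h for R848 + Pam3CSK4. Counts above the sum were 99 at 4 h for R848 + LPS and 0 (269) and 142 at 1 and 4 h for poly(I:C) + Pam3CSK4. Lying above the sum were 15 and 16 at 4 and 8 h for poly(I:C) + LPS and 1 and 37 at 1 and 4 h for Pam3CSK4 + LPS. Counts below the sum were 226 at 4 h for R848 + poly(I:C) and 78 at 1 h for R848 + Pam3CSK4. Lying below the sum were 5 and 341 at 1 and 4 h for poly(I:C) + Pam3CSK4 and 12 at 1 h for poly(I:C) + LPS. The numbers below the sum were 82 at 1 h for Pam3CSK4 + LPS. With each time on its own, genes above the sum numbered 0 (67) at 1 h for R848 + poly(I:C) and 0 (41) at 1 h for poly(I:C) + Pam3CSK4. Above the sum there were 2 at 8 h for poly(I:C) + LPS. Genes below the sum numbered 3 at 1 h for R848 + poly(I:C) and 1 at 1 h for poly(I:C) + Pam3CSK4. Below the sum there were 3 at 1 h for poly(I:C) + LPS. With the earlier of the repeat arrays, genes above the sum numbered 0 (77) at 1 h for R848 + poly(I:C) and 2 at 4 h for poly(I:C) + LPS. With any sum above 0, genes above the sum numbered 17 at 8 h for poly(I:C) + LPS. With a sum of at least the untreated level, genes above the sum numbered 3 and 5 at 4 and 8 h for poly(I:C) + LPS. Without the 3 extracts, genes above the sum numbered 0 (35) at 1 h for R848 + poly(I:C) and 2 at 8 h for R848 + Pam3CSK4. Above the sum there were 4 and 4 at 4 and 8 h for poly(I:C) + LPS. Counts below the sum were 389 at 8 h for R848 + poly(I:C) and 151 at 4 h for R848 + Pam3CSK4. Lying below the sum were 417 at 8 h for poly(I:C) + Pam3CSK4 and 50 at 1 h for Pam3CSK4 + LPS.

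The product of the single folds was tested for all 8039 genes, more than the sum. Against it, genes above this product numbered 2, 242 and 606 at 1, 4 and 8 h for R848 + poly(I:C) and 52, 1080 and 1131 at 1, 4 and 8 h for R848 + Pam3CSK4. Counts above it were 102, 1044 and 1170 at 1, 4 and 8 h for R848 + LPS and 2, 242 and 625 at 1, 4 and 8 h for poly(I:C) + Pam3CSK4. Lying above it were 2, 714 and 999 at 1, 4 and 8 h for poly(I:C) + LPS and 69, 764 and 1049 at 1, 4 and 8 h for Pam3CSK4 + LPS. The numbers below it were 43 and 185 at 1 and 4 h for R848 + poly(I:C) and 173, 772 and 846 at 1, 4 and 8 h for R848 + Pam3CSK4. Genes below it numbered 240, 835 and 953 at 1, 4 and 8 h for R848 + LPS and 41 at 1 h for poly(I:C) + Pam3CSK4. Below it there were 50, 642 and 966 at 1, 4 and 8 h for poly(I:C) + LPS and 188, 589 and 843 at 1, 4 and 8 h for Pam3CSK4 + LPS. Named genes that took the other sign were Cish with Pam3CSK4 + LPS at 4 h (-0.25 against 1.11), Gadd45g with R848 + poly(I:C) at 4 h (0.20 against -1.94), Hhex with R848 + poly(I:C) at 4 h (0.09 against -2.15), Il10 with Pam3CSK4 + LPS at 8 h (-1.68 against 0.72) and Il10 with R848 + poly(I:C) at 8 h (-1.41 against 0.87). So did Il10 with poly(I:C) + Pam3CSK4 at 8 h (-0.91 against 1.07), Il12a with Pam3CSK4 + LPS at 4 h (-0.28 against 1.24), Il27 with R848 + poly(I:C) at 4 h (-0.60 against 2.06) and Il6 with Pam3CSK4 + LPS at 8 h (-0.51 against 1.35).

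With the run of extract numbers as a block, genes whose response differed between 8 h and 4 h numbered 130 for Pam3CSK4 and 178 for R848 + Pam3CSK4. Genes above the sum numbered 3 at 1 h for R848 + poly(I:C) and 1 and 1 at 4 and 8 h for R848 + Pam3CSK4. Above the sum there were 73 at 4 h for R848 + LPS and 5 at 4 h for poly(I:C) + LPS. The sum was exceeded by 28 at 4 h for Pam3CSK4 + LPS. Counts below the sum were 178 at 4 h for R848 + poly(I:C) and 73 at 1 h for R848 + Pam3CSK4. Lying below the sum were 5 at 1 h for poly(I:C) + Pam3CSK4 and 52 at 1 h for Pam3CSK4 + LPS. With this block 70 of 82 counts stayed within 1.5 times. As a check of pairing by run, the correlations across genes of extract differences between groups had a median of 0.44 at 1 h (from 0.018 to 0.68), 0.27 at 4 h (from -0.0011 to 0.41) and 0.16 at 8 h (from -0.2 to 0.38). Of the 55 pairs of groups at each time 96.4, 96.4 and 70.9 percent exceeded 0.1. Most pairs of groups thus shared a shift by run or slide, least at 8 h.

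Leaving out each extract in turn gave these ranges, with the lone extract left in a group assumed to vary like the other groups. Called against untreated were 345 to 670 at 1 h for R848 and 63 to 255 at 1 h for poly(I:C). Between the times the counts were 71 to 102 for R848 and 300 to 1464 for poly(I:C). Differing between 8 h and 4 h were 38 to 70 for Pam3CSK4 and 73 to 161 for R848 + Pam3CSK4. The ligand contrasts gave 2 to 9 for R848 against Pam3CSK4. Counts above the sum were 0 to 16, 38 to 58 and 119 to 286 at 1, 4 and 8 h for R848 + poly(I:C) and 0 to 39 and 0 to 1 at 4 and 8 h for R848 + Pam3CSK4. Lying above the sum were 23 to 37 at 4 h for R848 + LPS and 0 to 2, 48 to 76 and 114 to 301 at 1, 4 and 8 h for poly(I:C) + Pam3CSK4. Genes above the sum numbered 0 to 2 and 2 to 74 at 4 and 8 h for poly(I:C) + LPS and 10 to 15 and 66 to 85 at 4 and 8 h for Pam3CSK4 + LPS. The numbers below the sum were 3 to 56, 66 to 97 and 352 to 1422 at 1, 4 and 8 h for R848 + poly(I:C) and 1 to 66, 77 to 461 and 110 to 318 at 1, 4 and 8 h for R848 + Pam3CSK4. Genes below the sum numbered 28 to 123 at 1 h for R848 + LPS and 1 to 77, 115 to 163 and 374 to 1442 at 1, 4 and 8 h for poly(I:C) + Pam3CSK4. Below the sum there were 3 to 87, 97 to 212 and 342 to 1286 at 1, 4 and 8 h for poly(I:C) + LPS and 6 to 35, 213 to 296 and 304 to 479 at 1, 4 and 8 h for Pam3CSK4 + LPS.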

Other observations

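The direct contrasts of each pair with its single ligands, and the genes named from them, were chosen only after the values were seen, and leaving out single extracts was not run for them. Some genes stood far lower with a pair than with 1 of its ligands alone. At 8 h Mmp9 was lower with R848 + LPS (-4.21 ± 0.39) and R848 + poly(I:C) (-2.94 ± 0.39) than with R848. It was also lower with Pam3CSK4 + LPS than with Pam3CSK4 (-3.59 ± 0.39) and with poly(I:C) + Pam3CSK4 than with Pam3CSK4 (-3.79 ± 0.39). Slc13a3 differed in these 4 contrasts by -3.72 ± 0.40, -1.86 ± 0.40, -3.35 ± 0.40 and -2.11 ± 0.40. Ccnd1 was lower with R848 + poly(I:C) (-4.89 ± 0.17), poly(I:C) + Pam3CSK4 (-3.32 ± 0.17) and poly(I:C) + LPS (-2.28 ± 0.17) than with poly(I:C).

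Adding a ligand to LPS changed fewer genes than adding LPS to another ligand. With R848 + LPS 87 higher and 41 lower genes were called against LPS at 8 h and 550 higher and 422 lower against R848. With Pam3CSK4 + LPS 87 higher and 28 lower against LPS and 549 higher and 405 lower against Pam3CSK4. With poly(I:C) + LPS 3 genes (Ifna5, Ifnb1 and Taf15) were higher and 8 lower than with LPS at 8 h (5 and 16 without the 3 extracts that stood apart). Among the lower was Pim1, a kinase (-1.93 ± 0.27, and -1.80 ± 0.27 at 4 h). Against poly(I:C) 520 higher and 430 lower were called (310 and 309 without those extracts). In limma 555 genes differed between poly(I:C) + LPS and LPS at 8 h at an unadjusted p under 0.05. R848 + Pam3CSK4 gave 0 called genes against R848 at 4 h and 0 at 8 h in limma, where 246 and 143 had an unadjusted p under 0.05. Against Pam3CSK4 8 were higher at 4 h (3 without those extracts) and 0 lower, with 666 at an unadjusted p under 0.05. At 8 h 6 were higher and 1 lower (Ccnd1), and 2 lower without those extracts.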
